A study of Mus musculus with 9 samples.

How the data were processed

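RNA was measured in 9 libraries of C2C12 myoblasts, 3 each of Control, Valine and Val+PA, and each library was assigned to its group by its label. The libraries were made from total RNA and described as strand-specific, per the labels' protocols, and sequenced as paired ends on an Illumina instrument. HISAT2, featureCounts, DESeq2 and the genome build GRCm38 are named in the submitters' processing notes without versions, order or settings, and the strand setting and annotation release of the counting are not given in the sources used here. The deposited count table holds whole-number read counts per gene and library, not normalized, with 53700 Ensembl gene IDs. The deposited normalized table holds an expression signal that, tested on the values, equals each gene's count times a factor for the gene and 1 factor per library. That signal is relative to gene length and to a library factor made by the authors, and it served only as an alternative unit. The 3 Val+PA columns carry a code shortened from the one in the labels and were matched by it.

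Gene symbols and coordinates were taken from the GENCODE M21 annotation of GRCm38, which gave a symbol to 52093 IDs (97%). A further 1553 IDs were not in that release, among them the 3 IDs with the most counts, which are named by ID only. No count went to an entry that names no gene. Where the counting could not separate near-identical copies, single genes are uncertain.

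Library totals ran from 26750226 to 35976589 counts, so that 1 count is 0.0271 to 0.0403 CPM. Genes were kept by the filterByExpr function of edgeR, which left 18415, and 20584 genes had no count in any library. Counts were scaled by TMM factors and fitted with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood method, with group means as the only terms and all 9 libraries in 1 fit, which leaves 6 residual degrees of freedom. Each of the 3 comparisons was a two-sided test with Benjamini-Hochberg adjustment at 0.05. Standard errors (SE) are the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic. They were not estimated directly and may be too small for genes with a few counts in a group. Levels are CPM after TMM scaling. Lists of genes, 39 in all, with 30 of pathways, 4 of RNA quality and 5 of cell type markers, were fixed before the data were examined, as were the tests and the rule for named genes. They were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted by Benjamini-Hochberg over the lists of a comparison, with an estimated correlation and fry as alternatives. The imprinted and iron handling lists were added later and adjusted together with the 39 others, over 41 lists.

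The genes named are, per comparison, the 5 largest rises and 5 largest falls among genes past the threshold with a mean of at least 2 CPM, a proper symbol and group values that do not overlap. To these come the called members of each pathway list with the largest rise and fall, or the member with the smallest p where none is called, and 12 genes fixed in advance, namely Plin2, Pdk4, Cpt1a, Angptl4, Cd36, Pparg, Fasn, Scd1, Sqstm1, Map1lc3b, Myod1 and Myog. Genes with under 10 counts in all libraries together were left out. The gene mt-Co1, Tfrc between Valine and Control, and the imprinted and iron handling genes fall outside the rule and were chosen after their values were seen, and Dcn is named as a member of a fixed marker list.

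The method was tested on simulated counts drawn from the real means and library sizes, with 200 genes changed by known folds. At 2-fold it recovered 29 of 50 genes for Valine against Control (17992 genes in the step), 41 of 50 for Val+PA against Valine (17988) and 32 of 50 for Val+PA against Control (17984). At 3-fold it recovered 43, 38 and 40 of 50, and 5, 9 and 11 unchanged genes were called. The criterion first set, recovery of 80% of all genes at 3-fold or more, failed in 1 of 6 combinations, which was Val+PA against Valine at 3-fold with 76%. That criterion was replaced, after this result was known, by recovery of 90% of changed genes with at least 1 CPM, which all 6 met. The simulated genes vary independently, so the test does not include shared shifts of a library such as those of Control 3 and Val+PA 2. A shifted simulated list gave a camera p of 3.52e-33 for Valine against Control and an unshifted one 0.497.

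Alternatives chosen before the data were examined were DESeq2 1.42.0, limma-voom, RLE and upper-quartile factors, library size alone, no filter, at least 1 CPM in 3 libraries, the 2 groups alone, a replicate block, leaving out each library, a stricter threshold of 0.01, and limma on log2 of the normalized signal plus 1 or plus 0.1 for genes with a mean of at least 0.5. Another 4 were added after the data had been seen, namely leaving out Control 3 and Val+PA 2 together, a trend on GC content per library, library quality weights, and counts thinned to the smallest total. No pair of libraries had counts alike within sampling noise, the lowest chi-square per degree of freedom within a group being 3.99, so all 9 were kept as separate replicates.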

Results

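C2C12 is a mouse myoblast line, a muscle precursor that divides in rich serum and fuses into myotubes when serum is withdrawn. RNA was sequenced from 9 libraries in 3 groups of 3. Control wells were collected after 12 h of starvation in OPTI-MEM, a reduced-serum medium. Valine wells received 0.45 mM valine, a branched-chain amino acid, for 36 h after the starvation. Val+PA wells received 0.45 mM valine for 24 h and 75 µM palmitic acid, a saturated fatty acid, for 12 h. Each group was 1 plate of 6 wells, from which 3 wells were drawn at random, so the p-values measure the spread among wells of 1 plate per group. The study's title places these groups in work on valine, intramuscular fat, autophagy and fatty acid metabolism.

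Library totals were 31561340, 32729454 and 26750226 counts in Control, 35928121, 33615481 and 33239051 in Valine and 35976589, 31866932 and 32446739 in Val+PA. One count was worth 0.0271 to 0.0403 CPM, the count scaled by the effective size of its library. Levels are given as mean ± SD in CPM with n = 3 libraries. On the plot of principal components the first component held 59.5% of the variance and parted the Control libraries, at -82.1 to -67.9, from all others, at 32.7 to 40.6. The second component held 15.2% and set Control 3, at -30, and Val+PA 2, at -58.8, apart from the other libraries of their groups. The mitochondrial transcript mt-Co1, picked after its values were seen, stood at 1229 CPM in Control 3 and 865 CPM in Val+PA 2, against 2935 to 5303 CPM elsewhere. Mitochondrial genes did not move together, since the median of the mitochondrially encoded list, as log2 CPM relative to the Control mean, was 1.09 in Control 3, -0.423 and -0.589 in the other Controls and -0.255 in Val+PA 2. The median SD of log2 CPM among libraries was 0.219 in Control, 0.0999 in Valine and 0.256 in Val+PA.

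**Figure D1:**
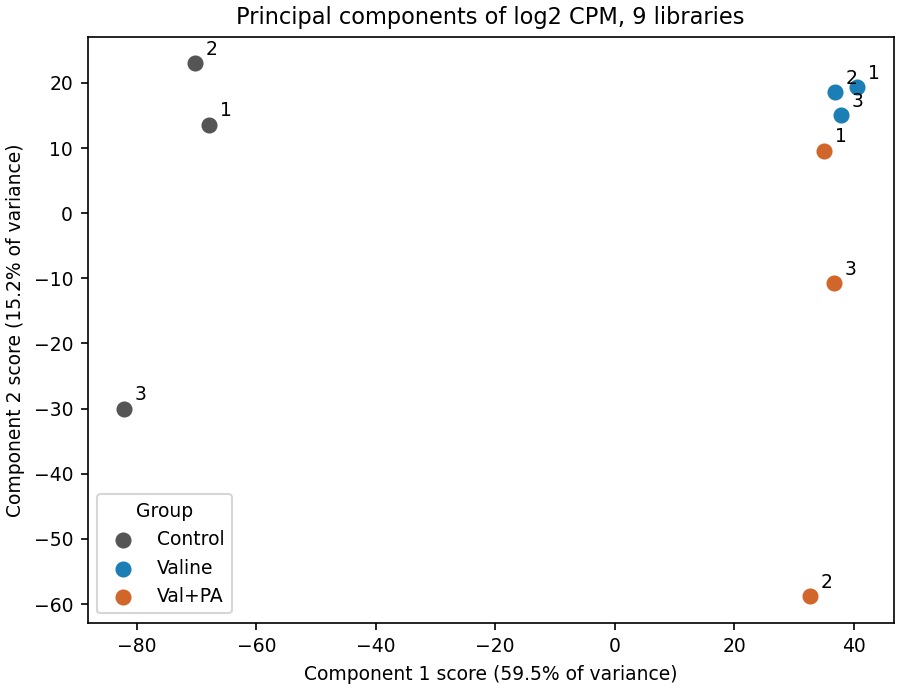
Scores of the 9 libraries on the first principal components of log2 CPM, component 1 (59.5% of the variance) on the x axis and component 2 (15.2%) on the y axis, with points coloured by group and numbered by replicate. Control lies on the left, and Control 3 (-30) and Val+PA 2 (-58.8) lie low on component 2.

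The first comparison, Valine against Control, asked what differed after 36 h with valine. Genes of cell division and cholesterol synthesis fell. Genes of the muscle contractile apparatus rose, as did interferon-response, extracellular matrix and integrated stress response genes, though limma camera gave these 4 lists a Benjamini-Hochberg adjusted p = 0.121, 0.103, 0.187 and 0.186 with an estimated correlation. Actc1, the cardiac actin of early myotubes, reached 30.3 ± 1.3 CPM (SD, n = 3) against 0.895 ± 0.048 CPM in Control, 33.6-fold higher. Ccne2, a cyclin of DNA replication onset, stood at 15.5 ± 2.1 CPM against 96.3 ± 8.5 CPM (SD, n = 3), 6.2-fold lower.

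Among 30 measured genes of sarcomere and contraction 25 rose and 2 fell, the same numbers adjusted over the list alone (limma camera, Benjamini-Hochberg adjusted p = 3.11e-10). The camera call was lost at an adjusted p = 0.121 with an estimated correlation. Actc1 (ENSMUSG00000068614, GRCm38 chromosome 2, 114047282 to 114053548, minus strand) rose by 5.07 on the log2 scale (SE 0.18, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.6e-08). Xirp1, an actin-binding repeat protein, was the member with the largest fall, at a log2 fold change of -1.39 (SE 0.19). Of 26 myogenic regulators 15 rose and 5 fell, with the same numbers adjusted over the list alone (limma camera, Benjamini-Hochberg adjusted p = 0.0127, adjusted p = 0.282 with an estimated correlation). Myog (ENSMUSG00000026459, chromosome 1, 134289989 to 134292548, plus strand), the transcription factor of terminal myoblast differentiation, rose from 0.487 ± 0.16 to 6.99 ± 0.51 CPM (SD, n = 3), a log2 fold change of 3.82 (SE 0.26). Mymx, which encodes a fusion micropeptide, rose by 4.02 (SE 0.35), and Id2, an inhibitor of myogenic factors, had a log2 fold change of -2.37 (SE 0.25). Myod1 measured 11.1 ± 1.3 CPM against 8.29 ± 1.2 CPM and did not pass the edgeR quasi-likelihood test (Benjamini-Hochberg adjusted p = 0.112). Without Control 3 and Val+PA 2, Myod1 passed that test, at a log2 fold change of 0.54 (SE 0.17, Benjamini-Hochberg adjusted p = 0.0136).

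All but 3 of the 50 measured cell cycle and DNA replication genes fell, 47 over all genes and 48 adjusted over the list alone, and none rose (limma camera, Benjamini-Hochberg adjusted p = 1.61e-22). That call held at an adjusted p = 0.00553 with an estimated correlation. Ccne2 (ENSMUSG00000028212, chromosome 4, 11191351 to 11204779, plus strand) had a log2 fold change of -2.63 (SE 0.21) and Cdc6, a replication licensing factor, one of -2.90 (SE 0.14). Histone genes that are transcribed with DNA replication moved alongside, 22 of 23 lower and none higher, the same adjusted over the list alone (limma camera, Benjamini-Hochberg adjusted p = 7.2e-12, adjusted p = 0.103 with an estimated correlation). Histone genes are near-identical copies, so single members are uncertain. Of 26 cholesterol synthesis genes 25 fell and none rose, the same adjusted over the list alone (limma camera, Benjamini-Hochberg adjusted p = 3.56e-16, adjusted p = 0.00299 with an estimated correlation). Lss, lanosterol synthase, had a log2 fold change of -1.97 (SE 0.13) and Acat2, a cytosolic acetoacetyl-CoA thiolase, one of -1.91 (SE 0.13). Hmgcs1 (ENSMUSG00000093930, chromosome 13, 119690379 to 119708260, plus strand), an early enzyme of that pathway, fell from 599 ± 51 to 270 ± 8.6 CPM (SD, n = 3).

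Chaperone and stress lists moved apart. Heat shock and proteasome genes fell in 24 of 35 cases, 25 adjusted over the list alone, and none rose (limma camera, Benjamini-Hochberg adjusted p = 5.46e-08, adjusted p = 0.00732 with an estimated correlation). Hsph1, a large heat shock protein, had a log2 fold change of -1.58 (SE 0.14). Hspa1b fell by 1.39 on the log2 scale, with its near-identical neighbour Hspa1a leaving the split of its reads uncertain. ER chaperones fell in 16 of 29 cases and rose in 5, the same adjusted over the list alone (limma camera, Benjamini-Hochberg adjusted p = 0.00792, adjusted p = 0.0806 with an estimated correlation). Integrated stress response genes rose in 22 of 35 cases, 25 adjusted over the list alone, and none fell (limma camera, Benjamini-Hochberg adjusted p = 8.03e-07, adjusted p = 0.186 with an estimated correlation). Fgf21 (ENSMUSG00000030827, chromosome 7, 45613886 to 45615490, minus strand), a hormone induced by amino acid stress, measured 3.01 ± 0.27 CPM against 0.0838 ± 0.08 CPM (SD, n = 3), a log2 fold change of 5.01 (SE 0.42) against a Control level of a few counts per library. Vldlr, a lipoprotein receptor, rose by 3.00 (SE 0.14). FOXO and muscle atrophy genes rose in 16 of 25 cases and fell in 1, the same adjusted over the list alone (limma camera, Benjamini-Hochberg adjusted p = 1.22e-06, adjusted p = 0.0123 with an estimated correlation). Pik3ip1, a restraint on phosphoinositide 3-kinase, rose by 2.55 (SE 0.12), and Pdk4 was the member that fell, at a log2 fold change of -1.01 (SE 0.13).

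Interferon-response genes rose in 26 of 33 cases, 28 adjusted over the list alone, and none fell (limma camera, Benjamini-Hochberg adjusted p = 2.03e-10, adjusted p = 0.103 with an estimated correlation). Ifi44 rose by 5.26 (SE 0.44) to 2.29 ± 0.5 CPM (SD, n = 3), and Oas2, an antiviral synthetase, rose by 4.46 (SE 0.33). Over the alternatives these log2 fold changes ran from 0.8 to 5.86 for Ifi44 and from 1.3 to 4.78 for Oas2, so their size is uncertain. Of 46 collagen and extracellular matrix genes 28 rose and 2 fell, the same adjusted over the list alone (limma camera, Benjamini-Hochberg adjusted p = 1.27e-08, adjusted p = 0.187 with an estimated correlation). Lum (ENSMUSG00000036446, chromosome 10, 97565128 to 97572703, plus strand), a matrix proteoglycan, showed a log2 fold change of 6.32 (SE 0.53), from 0.0792 ± 0.018 to 6.60 ± 0.91 CPM (SD, n = 3). Nid1, a basement membrane protein, had a log2 fold change of -0.53 (SE 0.11). Markers of fibroblasts and fibro-adipogenic progenitors moved in the same direction as the matrix genes, with 8 of 10 higher and 1 lower (limma camera, Benjamini-Hochberg adjusted p = 3.04e-05, adjusted p = 0.0274 with an estimated correlation), also 8 and 1 adjusted over the list alone. Lum and Dcn stand in both of these lists. Among mitochondrially encoded genes 5 of 13 fell and none rose, or 6 and none adjusted over the list alone, and camera did not call the list (Benjamini-Hochberg adjusted p = 0.146). Ribosomal protein genes fell in 20 of 76 cases and rose in 2, or 18 and 1 adjusted over the list alone (limma camera, Benjamini-Hochberg adjusted p = 0.0498, adjusted p = 0.305 with an estimated correlation), a call also lost without Control 1 (0.105), Valine 1 (0.0618), Valine 3 (0.0663) or Val+PA 3 (0.0525). Of 7 non-coding and ribosomal RNA genes 4 fell and 1 rose, or 5 and 1 adjusted over the list alone, without a camera call (Benjamini-Hochberg adjusted p = 0.137). Of 4 measured endothelial markers 3 rose and none fell, and of 5 immune markers 1 rose and 1 fell, with the same numbers adjusted over the list alone.

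Of 35 immediate early and serum response genes 23 fell and 3 rose, the same adjusted over the list alone (limma camera, Benjamini-Hochberg adjusted p = 4.23e-07, adjusted p = 0.13 with an estimated correlation). Spry4, a feedback inhibitor of receptor kinase signalling, had a log2 fold change of -2.98 (SE 0.18), while Atf3 rose by 1.06 (SE 0.14). NRF2 antioxidant genes fell in 17 of 29 cases and rose in 3, the same adjusted over the list alone (limma camera, Benjamini-Hochberg adjusted p = 0.000193, adjusted p = 0.0648 with an estimated correlation). Mt1, a metallothionein, had a log2 fold change of -2.28 (SE 0.18), whereas Slc7a11, a cystine transporter, rose by 0.85 (SE 0.14).

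Lipid and autophagy genes moved in both directions. Fatty acid oxidation genes rose in 12 of 30 cases and fell in 2, the same adjusted over the list alone (limma camera, Benjamini-Hochberg adjusted p = 0.0129, adjusted p = 0.282 with an estimated correlation). Acot2, a mitochondrial acyl-CoA thioesterase, rose by 1.61 (SE 0.13). Cpt1a, which admits long-chain fatty acids to mitochondria, measured 102 ± 5.2 CPM against 82.3 ± 19 CPM (SD, n = 3) and did not pass. Camera called none of the lists of fatty acid synthesis (2 higher and 4 lower of 24), triglyceride synthesis and lipid droplets (8 and 9 of 26), PPAR-responsive genes (7 and 3 of 22) or adipocyte markers (6 and 4 of 17), and each had the same numbers adjusted over the list alone. The adipocyte list had a median log2 fold change of -0.0234, a mean of 0.334 and an upward camera direction. Fasn, the fatty acid synthase, had a log2 fold change of -1.51 (SE 0.21), while Scd1, a fatty acid desaturase, rose by 0.86 (SE 0.09) to 2590 ± 44 CPM (SD, n = 3). Plin2 (ENSMUSG00000028494, chromosome 4, 86648386 to 86670060, minus strand), a lipid droplet coat protein, fell from 714 ± 58 to 527 ± 12 CPM (SD, n = 3), a log2 fold change of -0.44 (SE 0.11, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00793). Its relative Plin4 had one of -1.71 (SE 0.14). Cd36, a fatty acid transporter, rose by 2.08 (SE 0.41) but only to 1.21 ± 0.25 CPM. Angptl4 and Pparg, at log2 fold changes of -0.04 (SE 0.14) and -0.13 (SE 0.12), did not pass. Of 47 autophagy genes 19 rose and 5 fell, or 20 and 8 adjusted over the list alone, and camera gave a Benjamini-Hochberg adjusted p = 0.0586. Leaving out Control 3, Val+PA 1 or Val+PA 2 brought that limma camera Benjamini-Hochberg adjusted p to 0.044, 0.0486 and 0.0396. Library size alone gave 0.0343, the 2 groups alone 0.0439, leaving out both Control 3 and Val+PA 2 0.0188 and library quality weights 0.0295. Fry called the list too (Benjamini-Hochberg adjusted p = 0.000409). Camera did not call it with RLE factors, an estimated correlation, the filter of at least 1 CPM in 3 libraries or a replicate block. The list also stayed uncalled when Control 1, Control 2, any single Valine library or Val+PA 3 was left out. Calcoco1, an autophagy receptor, rose by 1.89 (SE 0.16) and Atg9b had a log2 fold change of -2.12 (SE 0.18). Sqstm1, the receptor p62, measured 851 ± 50 CPM against 1040 ± 41 CPM (SD, n = 3). Map1lc3b, the LC3B gene, measured 155 ± 7.3 CPM against 147 ± 8.8 CPM (SD, n = 3), and neither gene passed. Without Control 3 and Val+PA 2, Sqstm1 passed, at a log2 fold change of -0.29 (SE 0.07, edgeR quasi-likelihood Benjamini-Hochberg adjusted p = 0.00179), and Map1lc3b did not (0.0897). Valine and branched-chain amino acid breakdown genes rose in 9 of 27 cases and fell in 2, the same adjusted over the list alone, and camera did not call the list (Benjamini-Hochberg adjusted p = 0.0805).

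The largest rises by the rule for named genes were those of Lum, Gfral (log2 fold change 5.91, SE 0.38), Ranbp3l (5.14, SE 0.27), Actc1 and Colec10 (4.99, SE 0.21). Gfral encodes the receptor of the stress hormone GDF15, and its Control level of 0.0718 ± 0.046 CPM (SD, n = 3) was a few counts per library. The largest falls were those of Prr9 (-6.91, SE 0.43), Prl2c2 (-4.93, SE 0.35), Prl2c3 (-4.63, SE 0.29), Serpinb9e (-4.06, SE 0.33) and Nptx1 (-3.94, SE 0.20). Over the alternatives the log2 fold change of Prr9 ran from -7.43 to -4.04. Prl2c2, Prl2c3 and Serpinb9e belong to families of near-identical copies and their single values are uncertain.

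Of 18415 genes tested, 3834 were higher and 3884 lower in Valine (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05), of which 3080 had an absolute log2 fold change of at least 1. Values of the 2 groups did not overlap for 10859 of the tested genes, where chance gives non-overlap for 10% of genes. Valine wells were also 36 h later and on another plate than Control wells, and no well without valine at that time was measured here.

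**Figure D2:**
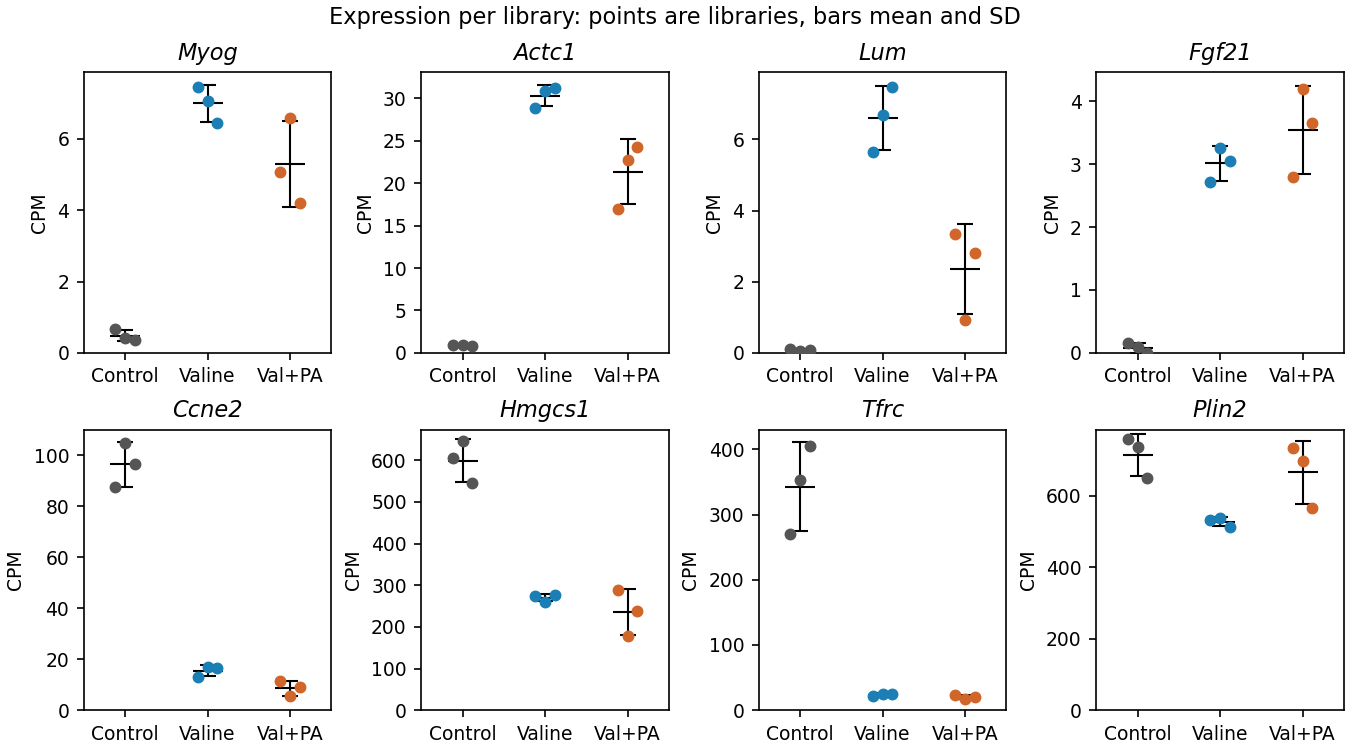
Expression of 8 genes per library, CPM on the y axis from 0 and the group on the x axis, where points are libraries and bars the mean ± SD of 3 libraries. Myog, Actc1, Lum and Fgf21 are higher and Ccne2, Hmgcs1, Tfrc and Plin2 lower in Valine than in Control, and Plin2 measured 665 ± 88 CPM in Val+PA.

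The second comparison, Val+PA against Valine, set 24 h of valine and 12 h of palmitic acid beside 36 h of valine. No single gene passed the edgeR quasi-likelihood test. The highest-ranked genes included Angptl4, an inhibitor of lipoprotein lipase, at 197 ± 32 CPM in Val+PA against 110 ± 4 CPM in Valine (SD, n = 3), and Ptgs2, the inducible cyclooxygenase, at 131 ± 44 CPM against 63.6 ± 3.1 CPM. As groups, PPAR-responsive, immediate early, integrated stress response, NRF2 antioxidant, cholesterol synthesis and lysosome genes stood higher, and cell cycle and sarcomere genes lower. These list calls rest on the preset correlation of camera and none held with an estimated one. Fry did not call the integrated stress response and sarcomere lists either (Benjamini-Hochberg adjusted p = 0.0662 and 0.225).

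Angptl4 (ENSMUSG00000002289, chromosome 17, 33773750 to 33781830, minus strand) had a log2 fold change of 0.85 (SE 0.14), Ptgs2 one of 1.05 (SE 0.19), Nr4a1, an immediate early nuclear receptor, one of 0.84 (SE 0.15), Plin4 one of 0.78 (SE 0.14), Slc27a1, a fatty acid transporter, one of 0.61 (SE 0.12), and Srxn1, which repairs peroxiredoxins, one of 0.57 (SE 0.10). Ttn, the giant sarcomere spring, measured 620 ± 69 CPM against 929 ± 12 CPM (SD, n = 3) and had a log2 fold change of -0.58 (SE 0.10). All of these 7 genes had an edgeR quasi-likelihood Benjamini-Hochberg adjusted p of 0.168. Of the genes fixed beforehand, Plin2 measured 665 ± 88 CPM against 527 ± 12 CPM (log2 fold change 0.34, SE 0.11), Pdk4 24.7 ± 2.6 CPM against 17.8 ± 2.3 CPM (0.48, SE 0.13) and Pparg 15.2 ± 1 CPM against 12.8 ± 0.8 CPM (0.25, SE 0.12). Smaller log2 fold changes were those of Cpt1a (0.05, SE 0.16), Scd1 (0.08, SE 0.08), Map1lc3b (0.15, SE 0.09), Sqstm1 (0.29, SE 0.12) and Fasn (0.30, SE 0.20). Those of Cd36 (-0.37, SE 0.34), Myod1 (-0.30, SE 0.20) and Myog (-0.40, SE 0.20) were negative.

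PPAR-responsive genes stood higher as a group of 22, with 0 called over all genes and 7 higher and none lower adjusted over the list alone (limma camera, Benjamini-Hochberg adjusted p = 3.96e-05, adjusted p = 0.188 with an estimated correlation). Immediate early and serum response genes did so too, 10 of 35 higher and none lower adjusted over the list alone (limma camera, Benjamini-Hochberg adjusted p = 1.74e-10, adjusted p = 0.123 with an estimated correlation). For the integrated stress response 1 of 35 genes was higher and none lower adjusted over the list alone (limma camera, Benjamini-Hochberg adjusted p = 1.55e-05, adjusted p = 0.359 with an estimated correlation), with Atf3 at a log2 fold change of 0.61 (SE 0.13). NRF2 antioxidant genes, 2 of 29 higher and none lower adjusted over the list alone, and lysosome genes, 2 of 47 higher and none lower, had the same values (limma camera, Benjamini-Hochberg adjusted p = 0.000212, adjusted p = 0.081 with an estimated correlation). Neu1, a lysosomal sialidase, stood at 51.2 ± 10 CPM against 31 ± 1.7 CPM (SD, n = 3). Cholesterol synthesis genes were higher as a group of 26 with none called adjusted over the list alone (limma camera, Benjamini-Hochberg adjusted p = 0.000673, adjusted p = 0.081 with an estimated correlation). Cholesterol medians relative to the Control mean overlapped, at -1.05, -1.01 and -1.18 in Val+PA and -1.14, -1.18 and -1.15 in Valine. Triglyceride synthesis and lipid droplet genes had 1 of 26 higher and none lower adjusted over the list alone (limma camera, Benjamini-Hochberg adjusted p = 0.00807, adjusted p = 0.359 with an estimated correlation). Matrix genes, at a limma camera Benjamini-Hochberg adjusted p = 0.0246, lost their call without Val+PA 2 (0.558) and had an adjusted p = 0.525 with an estimated correlation. Adipocyte markers, 5 of 17 higher and 1 lower adjusted over the list alone, had a limma camera Benjamini-Hochberg adjusted p = 0.0308 that was lost without Val+PA 1 (0.0677), and an adjusted p = 0.359 with an estimated correlation. Fatty acid oxidation and aminoacyl-tRNA synthetase genes had limma camera Benjamini-Hochberg adjusted p values of 0.0486 and 0.0463. These 2 lists lost their calls in most alternatives, including an adjusted p = 0.473 and 0.445 with an estimated correlation. The PPAR-responsive list shares 8 genes with fatty acid oxidation, 4 with triglyceride synthesis and lipid droplets and 4 with adipocyte markers. The results of these lipid lists are therefore not independent of each other. The 47 autophagy genes were not called, with none passing adjusted over the list alone (limma camera, Benjamini-Hochberg adjusted p = 0.106), nor were the 24 fatty acid synthesis genes, also with none (Benjamini-Hochberg adjusted p = 0.731 by limma camera).

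Cell cycle genes stood lower than in Valine, 15 of 50 lower and none higher adjusted over the list alone (limma camera, Benjamini-Hochberg adjusted p = 3.67e-12, adjusted p = 0.0581 with an estimated correlation). Mki67, a proliferation marker, measured 41.6 ± 3.1 CPM against 61.5 ± 4.1 CPM (SD, n = 3). Sarcomere genes had 3 of 30 lower and none higher adjusted over the list alone (limma camera, Benjamini-Hochberg adjusted p = 0.00996, adjusted p = 0.499 with an estimated correlation). The sarcomere call was lost without Val+PA 1 (limma camera, Benjamini-Hochberg adjusted p = 0.195) or without Val+PA 3 (0.13). Sarcomere medians relative to the Control mean overlapped, at 1.26, 1.63 and 1.35 in Val+PA and 1.44, 1.53 and 1.33 in Valine. Replication-dependent histone genes stood lower beside the cell cycle genes, with none called adjusted over the list alone (limma camera, Benjamini-Hochberg adjusted p = 0.00996, adjusted p = 0.499 with an estimated correlation). That histone call was lost without Val+PA 1 (limma camera, Benjamini-Hochberg adjusted p = 0.522) or without Valine 2 (0.137). Histone medians overlapped too, at -1.85, -1.31 and -1.69 in Val+PA and -1.62, -1.27 and -1.35 in Valine. Camera did not call the fibroblast markers (Benjamini-Hochberg adjusted p = 0.671), with 1 of 10 lower and none higher adjusted over the list alone, which was Lum at 2.36 ± 1.3 CPM against 6.60 ± 0.91 CPM (SD, n = 3).

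The edgeR quasi-likelihood test called 0 genes, the smallest Benjamini-Hochberg adjusted p being 0.168, with 2428 genes at an unadjusted p under 0.05 where chance gives 921. DESeq2 called 192 genes and limma-voom 0, and edgeR without a filter on low counts called 763. Without that filter edgeR tested 33116 genes and its smallest Benjamini-Hochberg adjusted p became 2.65e-22. The 763 calls thus depend on adding genes with low counts to the fit, and the reason was not tested. Left out after the data had been seen, the pair of libraries Control 3 and Val+PA 2 made a difference here, since edgeR then called 312 genes higher and 292 lower. The pair was picked for standing apart, which by itself favours a smaller spread and more calls. Control 3 is in neither group compared and enters only through the shared fit, and Val+PA keeps 2 libraries. Leaving out either library alone gave 0 genes. Calls without the pair included Angptl4 (log2 fold change 0.74, SE 0.08), Ptgs2 (1.20, SE 0.13), Plin4 (0.61, SE 0.09), Ttn (-0.63, SE 0.07) and Mki67 (-0.56, SE 0.08), 22 of 50 cell cycle genes lower and 5 of 22 PPAR-responsive genes higher. Lists of RNA quality moved there too, with 12 of 23 replication-dependent histone genes lower and 1 higher, and 5 of 13 mitochondrially encoded genes higher and none lower. The mitochondrial list had a limma camera Benjamini-Hochberg adjusted p = 0.00212 without the pair against 0.141 over all libraries. Among cell type markers, 2 of 6 neural and glial genes were lower and none higher without the pair (limma camera, Benjamini-Hochberg adjusted p = 0.00662, against 0.103 over all libraries), and 2 of 10 fibroblast markers were lower and none higher, without a camera call (Benjamini-Hochberg adjusted p = 0.305). Of the genes fixed beforehand, edgeR without the pair also called Pdk4 (log2 fold change 0.56, SE 0.1, Benjamini-Hochberg adjusted p = 0.00587) and Myog (-0.59, SE 0.15, 0.044). Apart from Angptl4, the other fixed genes did not pass, among them Plin2 (edgeR quasi-likelihood Benjamini-Hochberg adjusted p = 0.0518). Myogenic regulators, 4 of 26 lower and 0 higher, gained a downward call that was absent over all libraries (limma camera, Benjamini-Hochberg adjusted p = 0.000327). The labels do not say whether valine stayed during the 12 h with palmitic acid, so palmitic acid, the time with valine (24 h against 36 h) and the plate are not separated.

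**Figure D3:**
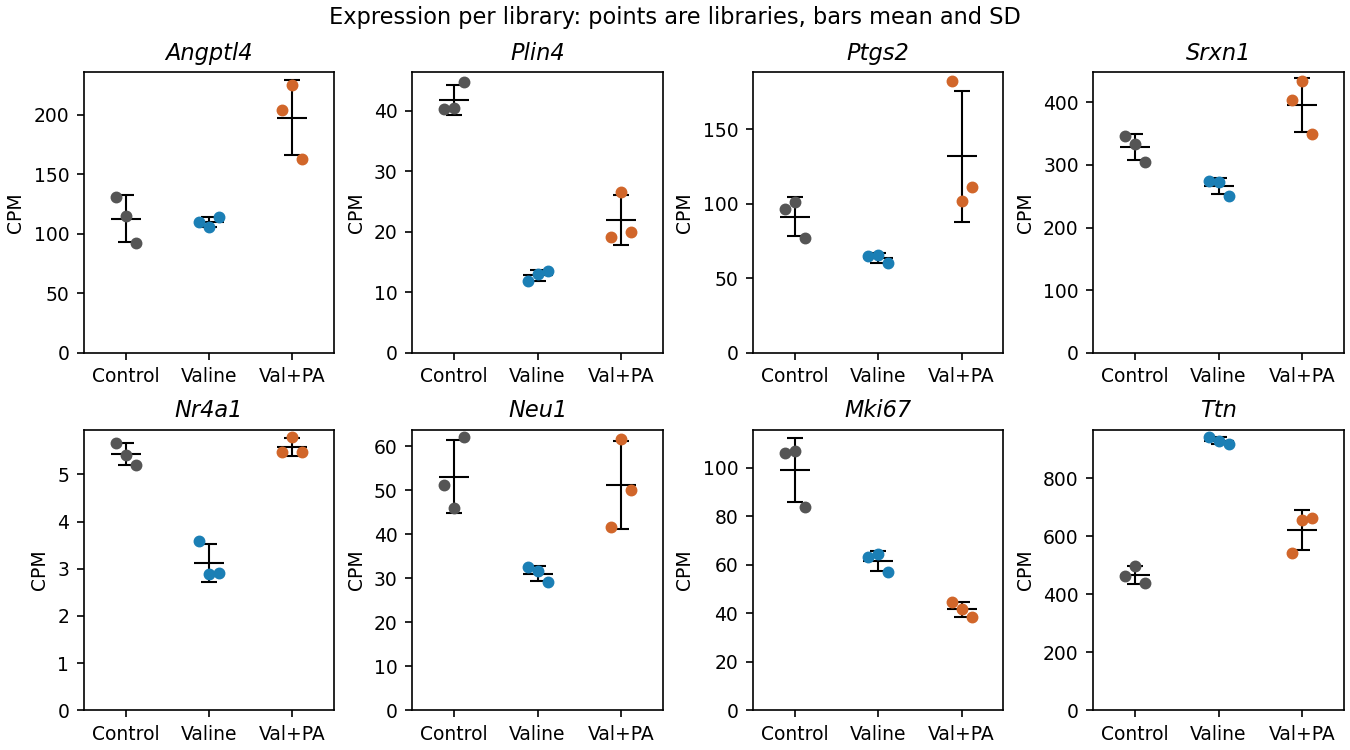
Expression of 8 genes per library, CPM on the y axis from 0 and the group on the x axis, where points are libraries and bars the mean ± SD of 3 libraries. Angptl4 measured 197 ± 32 CPM in Val+PA and 110 ± 4 CPM in Valine, and Ttn 620 ± 69 and 929 ± 12 CPM, with no gene past the edgeR test between these groups.

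The third comparison, Val+PA against Control, took both treatments and the elapsed time together. Cell division and cholesterol genes fell, as in Valine against Control. Sarcomere, matrix, interferon and integrated stress response genes rose, though limma camera gave them a Benjamini-Hochberg adjusted p = 0.12, 0.11, 0.106 and 0.106 with an estimated correlation. Myog rose to 5.29 ± 1.2 CPM (SD, n = 3), a log2 fold change of 3.41 (SE 0.26), and Fgf21 rose by 5.25 (SE 0.41). Ccne2 had a log2 fold change of -3.48 (SE 0.22) and Idi1, an isomerase of cholesterol synthesis, one of -2.03 (SE 0.18). Angptl4 rose from 113 ± 20 to 197 ± 32 CPM (SD, n = 3), a log2 fold change of 0.81 (SE 0.14, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00086).

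Cell cycle genes fell in 49 of 50 cases, all 50 adjusted over the list alone, and none rose (limma camera, Benjamini-Hochberg adjusted p = 7.15e-29, adjusted p = 0.00273 with an estimated correlation). Replication-dependent histone genes fell beside them in 21 of 23 cases and none rose, the same adjusted over the list alone (limma camera, Benjamini-Hochberg adjusted p = 3.35e-13, adjusted p = 0.106 with an estimated correlation). Cholesterol synthesis genes fell in 23 of 26 cases, 24 adjusted over the list alone, and none rose (limma camera, Benjamini-Hochberg adjusted p = 2.79e-14, adjusted p = 0.00273 with an estimated correlation). Sarcomere genes rose in 24 of 30 cases and fell in 2, or 25 and 2 adjusted over the list alone (limma camera, Benjamini-Hochberg adjusted p = 2.71e-09, adjusted p = 0.12 with an estimated correlation). Matrix genes rose in 30 of 46 cases and fell in 1, or 33 and 1 adjusted over the list alone (limma camera, Benjamini-Hochberg adjusted p = 1.38e-12, adjusted p = 0.11 with an estimated correlation), and the fibroblast markers beside them rose in 8 of 10 cases, also 8 adjusted over the list alone. Integrated stress response genes rose in 24 of 35 cases and interferon-response genes in 25 of 33, or 25 and 25 adjusted over the list alone, and none of either fell. Camera gave these lists Benjamini-Hochberg adjusted p values of 1.61e-10 and 1.45e-09, and for each an adjusted p = 0.106 with an estimated correlation. Other stress lists fell, heat shock and proteasome genes in 21 of 35 cases with none higher, the same adjusted over the list alone (limma camera, Benjamini-Hochberg adjusted p = 7.01e-07, adjusted p = 0.0116 with an estimated correlation). ER chaperones fell in 17 of 29 cases and rose in 5, or 18 and 6 adjusted over the list alone (limma camera, Benjamini-Hochberg adjusted p = 0.0155, adjusted p = 0.106 with an estimated correlation). NRF2 antioxidant genes fell in 14 of 29 cases and rose in 2, or 14 and 5 adjusted over the list alone (limma camera, Benjamini-Hochberg adjusted p = 0.0129, adjusted p = 0.12 with an estimated correlation). PPAR-responsive genes rose in 8 of 22 cases and fell in 1, the same adjusted over the list alone (limma camera, Benjamini-Hochberg adjusted p = 0.00569, adjusted p = 0.245 with an estimated correlation). Autophagy genes rose in 18 of 47 cases and fell in 4, the same adjusted over the list alone (limma camera, Benjamini-Hochberg adjusted p = 0.00569, adjusted p = 0.106 with an estimated correlation). Fatty acid oxidation genes rose in 13 of 30 cases and fell in 3, or 14 and 3 adjusted over the list alone (limma camera, Benjamini-Hochberg adjusted p = 0.00113, adjusted p = 0.18 with an estimated correlation). The fatty acid oxidation and PPAR-responsive lists share 8 genes.

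Scd1 rose by 0.94 (SE 0.09), Cd36 rose by 1.72 (SE 0.42) and Acot2 by 2.12 (SE 0.13), while Fasn and Pdk4 had log2 fold changes of -1.21 (SE 0.21) and -0.54 (SE 0.13). Plin2, Pparg, Cpt1a, Sqstm1, Map1lc3b and Myod1 did not pass the edgeR test here. Plin2 measured 665 ± 88 CPM against 714 ± 58 CPM (SD, n = 3). Without Control 3 and Val+PA 2, Cpt1a (log2 fold change 0.24, SE 0.09) and Map1lc3b (0.26, SE 0.07) passed that test. Their edgeR quasi-likelihood Benjamini-Hochberg adjusted p values were 0.0299 and 0.00476, and the others still did not pass. The largest rises by the rule for named genes were those of Gfral (log2 fold change 6.09, SE 0.38), Car6 (4.77, SE 0.17), Satb1 (4.72, SE 0.14), Cilp (4.71, SE 0.25) and Ranbp3l (4.64, SE 0.27). The largest falls by that rule were those of Prr9, Prl2c2 (-5.46, SE 0.36), Prl2c3 (-4.93, SE 0.29), Tfrc (-4.08, SE 0.18) and Nptx1 (-3.60, SE 0.19). Prr9 went from 10.8 ± 4.2 CPM to 0.0197 ± 0.017 CPM (SD, n = 3), a level of under 1 count per library on average that carries no usable fold. Tfrc (ENSMUSG00000022797, chromosome 16, 32608920 to 32632794, plus strand), the transferrin receptor, fell from 343 ± 68 to 20.2 ± 3.2 CPM (SD, n = 3).

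**Figure D4:**
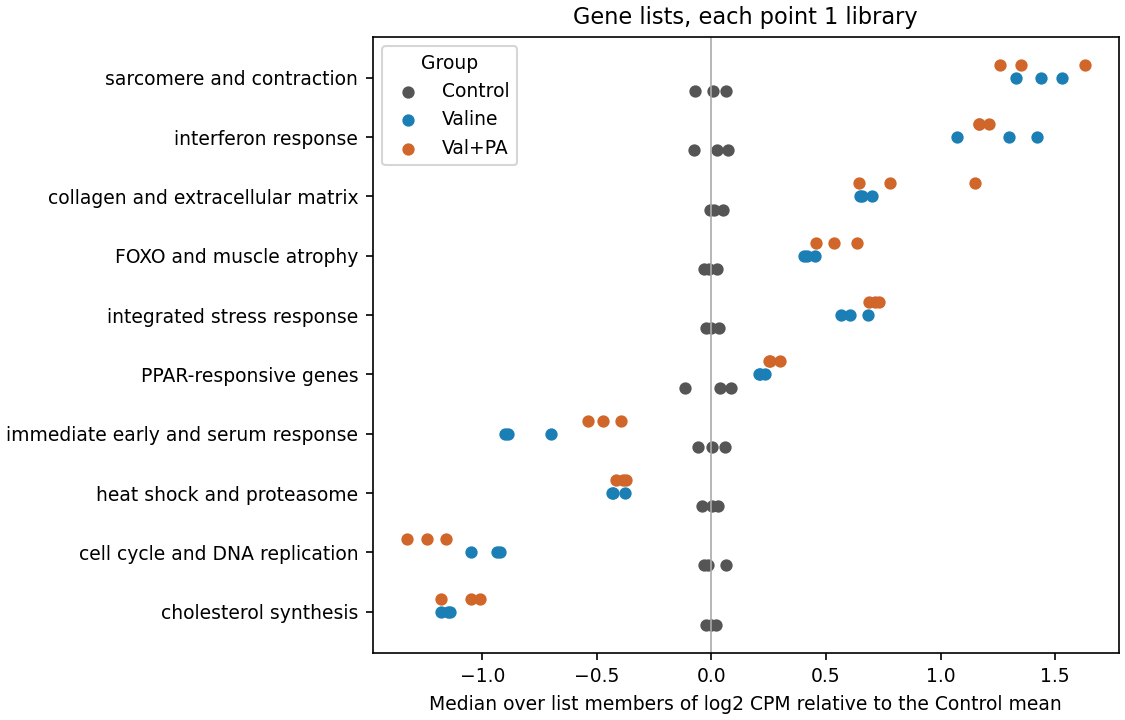
Gene lists named on the y axis, with the median over members of log2 CPM relative to the Control mean on the x axis, where each point is 1 library coloured by group. Sarcomere genes lay between 1.33 and 1.53 in Valine and between 1.26 and 1.63 in Val+PA, and cell cycle and cholesterol synthesis genes lay below 0 in all libraries of both groups.

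Of 18415 genes tested, 3748 were higher and 3471 lower in Val+PA than in Control (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05), of which 2885 had an absolute log2 fold change of at least 1. The calls of this comparison and of Valine against Control had 5863 genes in common in the same direction, 3042 higher and 2821 lower, and 1 in opposite directions. Independent lists of these sizes would have 780 higher and 732 lower in common, and simulated unchanged groups against the same Controls had 0.1 on average and at most 1. Across genes, which are not independent replicates, the log2 fold changes had a correlation of 0.916 and a covariance of 0.745, against 0.514 and 0.0413 in the simulation. The 3 Controls cannot be split into parts of at least a pair each, so part of the excess may come from the shared Controls. No gene called in Valine against Control was called with the opposite sign in Val+PA against Valine by the edgeR test. That test called none there at all, whereas DESeq2 gave 102 such genes and 52 of the same sign. The same Valine libraries stand on opposite sides of these comparisons, so their noise alone favours opposite signs.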

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

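Of these alternatives, leaving out Control 3 and Val+PA 2 together, the GC trend, the library quality weights and the thinning were chosen after the data had been seen. No gene called between Valine or Val+PA and Control changed sign under any alternative. Genes differing between Valine and Control numbered 7718, of which 3080 had an absolute log2 fold change of at least 1 and 5092 passed at 0.01, and for Val+PA and Control 2885 of 7219 reached that fold change. Leaving out single libraries gave 5796 to 9244 and 6043 to 7863 genes. Between Val+PA and Valine each single library left out gave 0 genes, as did limma-voom, while DESeq2 gave 192, no filter 763, leaving out both libraries 604, the GC trend 7 and the quality weights 891. Genes called between Valine and Control and again with the opposite sign between Val+PA and Valine, 0 by edgeR, numbered 102, 407, 295, 4 and 408 under these alternatives in that order, against 52, 118, 220, 2 and 273 with the same sign. For both counts the cause was not tested. The Valine libraries stand on opposite sides of these comparisons, so their noise alone favours opposite signs. Calls common to both comparisons with Control ranged from 4817 to 7061 as single libraries were left out. Of 39 lists, camera called 17, 14 and 19 for Valine against Control, Val+PA against Valine and Val+PA against Control, an estimated correlation 5, 0 and 5, and fry, which does not compare a list with other genes, 29, 8 and 31. Single libraries left out gave 15 to 18, 10 to 16 and 18 to 22 lists. Upper-quartile factors moved the share of higher genes from 49.7% to 55.5% between Valine and Control. Libraries with the same number did not deviate together, the correlations of their deviations running from -0.27 to 0.16, so the numbers do not pair wells, and a replicate block gave 7369, 0 and 6935 genes. Among named genes 44 values lost and 109 gained a call over all alternatives, with 4296 staying on their side of the threshold, and for lists these numbers were 90, 64 and 1949. With 1 count worth up to 0.0403 CPM, genes below 0.1 CPM in a group rest on a few counts.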

Other observations

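The tests of imprinted and iron handling genes, of single libraries, GC content, abundant IDs, exchanged labels, depth and elapsed time were chosen only after the result was seen, unlike the splits of the libraries. Imprinted genes, which are expressed from 1 parental copy, stood higher in Valine than in Control, with 8 of 15 higher and 1 lower (limma camera, Benjamini-Hochberg adjusted p = 1.46e-03 over 41 lists, adjusted p = 0.0584 with an estimated correlation), so whether they move as a group stays open. H19, a long non-coding RNA of growth control, had a log2 fold change of 2.59 (SE 0.18), Zim1 of 2.22 (SE 0.14), Igf2r, which clears insulin-like growth factor, of 1.30 (SE 0.11), and Peg3 of 1.04 (SE 0.10), while Impact, a regulator of the GCN2 stress kinase, had one of -0.95 (SE 0.13). In Val+PA against Valine the list pointed down with 0 genes called by edgeR (limma camera, Benjamini-Hochberg adjusted p = 0.00588, adjusted p = 0.108 with an estimated correlation). In Val+PA against Control 7 were higher and 1 lower (limma camera, Benjamini-Hochberg adjusted p = 0.00968, adjusted p = 0.102 with an estimated correlation).

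Of 13 iron handling genes 9 were lower and 3 higher in Valine (limma camera, Benjamini-Hochberg adjusted p = 0.0179 over 41 lists, adjusted p = 0.102 with an estimated correlation), and a shift of the list as a whole stays open too. In Val+PA against Control 6 were lower and 2 higher and camera did not call the list (Benjamini-Hochberg adjusted p = 0.0862). In Val+PA against Valine it pointed up with 0 genes called by edgeR (limma camera, Benjamini-Hochberg adjusted p = 0.0332, adjusted p = 0.187 with an estimated correlation). Tfrc, the iron importer, had a log2 fold change of -3.84 (SE 0.18), the ferritin chains Fth1 and Ftl1 had ones of -0.81 (SE 0.11) and -1.05 (SE 0.13), and the exporter Slc40a1 rose by 2.58 (SE 0.11). Both lists were put together after some of their members had been seen among changed genes, so their tests are hypotheses on the same data.

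Control 3 and Val+PA 2 stand apart from the other libraries of their groups. For Control 3, a trend on GC content took up 4.81% of the variance of its difference from the others, which argues against that trend. The 3 most abundant IDs took 10.8% of its counts against at most 6.05% in the 7 libraries that do not stand apart. Of these IDs, ENSMUSG00000118642 took 6.19% in Control 3 against 1.45% in both Control 1 and Control 2. The others took 2.313% and 2.315%, against 2.312% and 2.288% in Control 1 and 1.645% and 1.63% in Control 2. The largest excess was thus that of 1 ID. TMM factors take up a shift shared by all genes, so this share cannot say why single genes of Control 3 differ. For Val+PA 2, the GC trend took up 60.3% and the most abundant IDs 5.39%. That leaves a GC bias of that library as a candidate explanation and argues against a raised summed share of the 3 abundant IDs. By itself, ENSMUSG00000118642 took 0.798% in Val+PA 2, against 0.2965% in Val+PA 1 and 0.6632% in Val+PA 3. Its share in Val+PA 2 was below the 1.45% of Control 1 and Control 2, which do not stand apart. Whether this ID bears on Val+PA 2 was not tested. The GC trend also took up 42.6% for Val+PA 1 and 35.3% for Val+PA 3, with the opposite sign. Each of these differences is taken from the mean of the group's other 2 libraries, so these values are not independent of Val+PA 2. Exchanged labels are argued against over 9285 genes called between Val+PA and Control without these 2 libraries, where Control 3 lay at 0.96 and Val+PA 2 at 0.05 on a scale from the other Val+PA libraries at 0 to the other Controls at 1. No biological explanation was tested, since the wells of a group were treated alike.

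Genes that differ between Valine and Control number 7718. Depth is argued against, since edgeR called 7506 genes after all libraries were thinned to the smallest total, 7308 of them among the 7718 and in the same direction. Elapsed time of 36 h and plate cannot be told apart from valine, because no well without valine at that time was measured here. With 10 splits of the 6 libraries no share under 0.05 can be reached, the real split giving 7718 genes and the highest other 0. For Val+PA against Control the real split gave 7219 and the highest other 1, and for Val+PA against Valine all 10 splits gave 0, with the same limit.

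PPAR-responsive genes stood higher and cell cycle genes lower in Val+PA than in Valine, by limma camera calls that are lost at Benjamini-Hochberg adjusted p = 0.188 and 0.0581 with an estimated correlation. Val+PA 2 alone is argued against, since without it camera of limma gave Benjamini-Hochberg adjusted p values of 6.15e-06 and 9.16e-19. A GC trend is argued against too, since taking it out left median log2 fold changes of 0.22 from 0.24 and -0.22 from -0.26. A response to palmitic acid remains a hypothesis that was not tested. The time with valine, 24 h against 36 h with its presence beside palmitic acid not stated, and a difference between the 2 plates stay open as untested.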
